A study of Bombyx mori with 13 samples.

How the data were processed

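The data were small RNA sequencing reads from immunoprecipitates of BmN4 cells, in 13 libraries of 8 groups. The deposited values were counts: per the file headers, the 7 genome-aligned files gave the number of reads per distinct sequence, with 1 genome position and 1 annotation for each. The 6 files of reporter-transfected cells listed single reads placed on the reporter, so their unit was also deposited counts, of reporter reads only. Reads were processed with cutadapt and Bowtie, per the submitters' processing notes, which give no versions. The genome build, the mismatch setting, the handling of reads with several matches and the source of the annotation were not given in the sources used here, and positions are printed as the files give them. A column of the reporter files named M has no stated meaning and was not used here. Per the labels' protocols, DQAD piRNA replicate 1, DQAD 12-mer replicate 2 and the long RNA library were made with homemade adaptors and the others with the NEBNext kit.

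Depth ranged from 1898800 to 2549478 reads in the piRNA libraries, with 415373 distinct sequences in Siwi, 413491 in Ago3, and 465619 and 912232 with DQAD. At these depths 3 counts, the floor used for a count of 0, stand for 1.18 to 1.58 RPM. The 12-mer libraries held 4280400 and 29265749 reads. Shares of single libraries carry 95% Wilson intervals, and group values are means with SD over n = 2.

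The reporter was rebuilt from its reads: each of 1109 positions was covered, and all 672601 reads equalled the rebuilt sequence. It held 14 sites of 28 nt at steps of 78 nt, and the site number n has its guide 5′ end at position 78 times n, from 78 to 1092. A sense read was counted as a product when its 5′ end gave a 10-nt overlap with the guide. Reads of the libraries without the reporter were matched to the same sequence, from 15 nt, or 12 nt for the 12-mers.

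Base composition was counted in reads of 26 to 30 nt (10 to 14 nt for 12-mers). Ping-pong overlaps of 1 to 20 nt were counted from genome positions, and the z score sets 10 nt against the others. A piRNA species was defined by its first 20 nt and classed by a 2-fold difference in RPM (reads scaled by library size) between the untransfected immunoprecipitates, with at least 10 reads. The 12-mers were compared with piRNA sequences at offsets 0 to 14 inside the piRNA rather than by position, because only 10.7% and 15.3% of their sequences were placed on the plus strand. A shuffled set of 50000 sampled 12-mers gave the chance level. Long reads were scored by any 20-nt stretch equal to the first 20 nt of a piRNA, its reverse complement or its reversed sequence. The 14 microRNAs were matched on their first 18 nt. Genome coordinates of 12-mers with several matches are 1 of several possible places.

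Features were tested with edgeR 4.0.16 (TMM, quasi-likelihood F test), DESeq2 1.42.0 (Wald test) and camera of limma 3.58.1, in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Features with at least 10 reads in at least 2 libraries were kept, and Benjamini-Hochberg adjusted p at or below 0.05 was called. For Ago3 against Siwi the features were 5′ ends by strand on the reporter, relative to reporter reads. For DQAD against Siwi or Ago3 they were annotation names, of which 2098 of 10792 were tested. Correlations over sites used 100000 permutations. For them r was taken on shares on a log scale with a small constant added, and rho on ranks. The named items are, per test, the 10 largest rises and the 10 largest falls among calls with a mean of at least 100 CPM and no overlap between the libraries of the groups, with the 5 most abundant sequences of each group. For the reporter test 125 features met this rule, for DQAD against Ago3 1, and for DQAD against Siwi none. None of 9364 gene model identifiers matched the reference table, so gene models are printed by identifier only.

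The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The files then forced changes. The planned fit over 3 groups was not possible because the reporter files hold reporter reads only, so the reporter test used the 2 reporter groups and the DQAD tests used the untransfected libraries, 1 each. The planned test of the reporter effect on 12-mers was not run, as the files share neither features nor library totals. Annotation names carry no strand. For the lists, tRNAs were recognised by amino acid and anticodon, RF and bmo- names were added to other RNA, and names with non_LTR were kept out of the LTR list. Ago3 and Siwi from untransfected cells, 1 library each, are given as values only. Alternatives added after seeing the data were the DQAD tests and lists without the second set of repeat names, and the reporter test with sense or antisense ends scaled among themselves.

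The procedures were tested on simulated data. A planted 10-nt overlap of 30% was recovered at 30.2%, and 12-mers planted at offset 5 in 40% of reads were recovered at offset 5 in 40.0%. Count tests were first simulated with a low dispersion of 0.05 only, where the reporter test recovered 100% of changes of log2 2 and of log2 4 (184 features, 0 of 120 unchanged called), and DQAD against Siwi recovered 94.9% and 100% (1827 features, 10 of 1627 unchanged called). The dispersion estimated from the libraries was simulated afterwards. At that spread the reporter test (0.146) recovered 65.5% of changes of log2 2 and 100% of log2 4 (182 features, 0 of 118 unchanged called), and DQAD against Siwi (0.552) recovered 0% of either (1724 features, 0 of 1524 unchanged called), so 0 calls in that test say little.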

Results

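Small RNAs bound to PIWI proteins and to the RNA helicase Vasa were sequenced from BmN4 cells, an ovary-derived cell line of the silkworm Bombyx mori with an active piRNA pathway. piRNAs are small RNAs that guide PIWI proteins to transposon transcripts, and BmN4 cells hold a pair of these proteins, Siwi and Ago3. The study asked how Vasa brings them together on a transposon transcript. It used DQAD, an ATPase mutant of Vasa carrying an HA tag, which was immunoprecipitated with the RNA bound to it. The 13 libraries fall into 8 groups. Siwi and Ago3 immunoprecipitates from untransfected cells had 1 library each. DQAD immunoprecipitates gave 2 libraries of piRNA size, 2 of about 12 nt (12-mers) and 1 of long RNA. Cells transfected with an artificial piRNA reporter gave 2 Siwi, 2 Ago3 and 2 DQAD 12-mer libraries. The genome-aligned piRNA libraries held between 1898800 reads (DQAD replicate 1) and 2549478 reads (DQAD replicate 2), with 2453207 for Siwi and 2259000 for Ago3. The 12-mer libraries held 4280400 and 29265749 reads and the long RNA library 57550129. The files of reporter-transfected cells held reporter reads only, from 37027 and 90407 for Ago3 to 183950 and 139680 for Siwi, with 110907 and 110630 for the 12-mers. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and all intervals and floors cover counting error only.

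Siwi and Ago3 bound piRNAs with opposite base signatures, and by read counts the piRNAs with DQAD lay closer to those of Siwi. Among reads of 26 to 30 nt, U at position 1, the mark of a primary or Siwi-bound piRNA, was found in 87.9% of Siwi reads and 39.97% of Ago3 reads. A at position 10, the mark left by cleavage opposite a guide that starts with U, was found in 39.8% and 81.1%. In the DQAD replicates U1 reached 69.9% and 65.8%, and A10 49.4% and 43.2%. Counting each distinct sequence once, U1 with DQAD (49.0%) lay next to Ago3 (45.6%) and far from Siwi (73.0%), while A10 (40.4%) lay next to Siwi (38.6%). Reads with neither base made up 5.58% of the Siwi, 9.69% of the Ago3 and 12.9% and 17.1% of the DQAD libraries. The most frequent length was 28 nt for Siwi, 27 nt for Ago3, and 27 and 28 nt for the DQAD replicates. Wilson 95% intervals were narrow, 87.8% to 87.9% for U1 in Siwi and 81.1% to 81.2% for A10 in Ago3. Each PIWI group has a single untransfected library, so these differences have no replicate check. The DQAD libraries came from cells holding the tagged mutant, so a difference from the PIWI libraries may also be one between experiments. DQAD replicate 1 was the only one of these libraries made with homemade adaptors, and within the NEBNext kit the DQAD value is that of replicate 2.

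**Figure D1:**
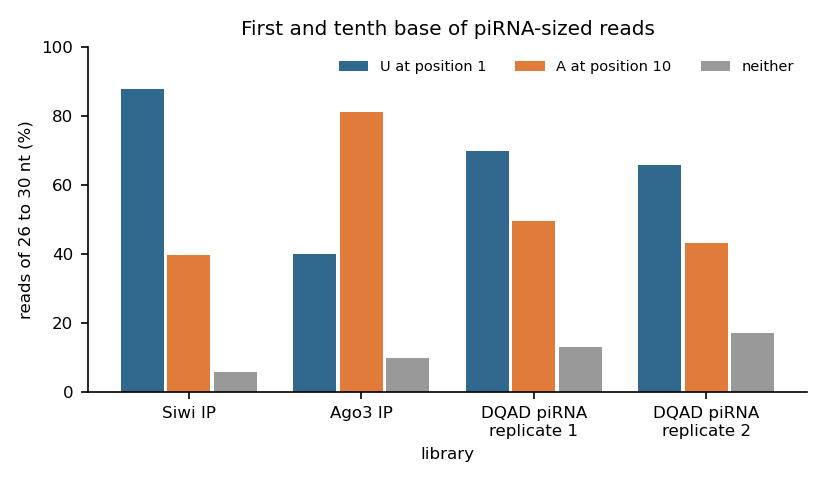
Share of reads of 26 to 30 nt (vertical axis, %) with U at position 1, A at position 10 or neither, in each of 4 libraries (horizontal axis), 1 bar per library and class. U1 is highest in Siwi (87.9%) and A10 in Ago3 (81.1%), and both DQAD bars for U1 (69.9% and 65.8%) lie between the PIWI values.

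The most abundant piRNA in Siwi, TGACTGCAAAATAGGTGATTCTTGATGC, on chromosome 10 from 1445130 to 1445157 (minus strand, no annotation), had 10349 reads or 4219 RPM (reads scaled by library size), and it also led DQAD replicate 2 with 1561 RPM. The highest Ago3 piRNA, ACCAACTGTCCCTCCTCCACGTGTACGT, lay on chromosome 5 from 20899239 to 20899266 (minus strand) with 5466 RPM. The Siwi piRNA TGTTGCAATTCCCACGACTGACGTACAC, on the plus strand of the same region from 20899219 to 20899246, stood at 2517 RPM in Siwi and is the guide of reporter site 1. Transfer RNA fragments ranked high too: TCTTCGGTAGTATAGTGGTCAGTATCCC, annotated Asp(GTC) on chromosome 24 from 4439442 to 4439469, had 2415 RPM in Siwi. In DQAD replicate 1 the leading sequence was GCACTGATTTAGGAGGATAGGAGAAGAC on chromosome 11 from 6602374 to 6602401, with 6173 RPM. Between 65.1% and 71.2% of reads in these 4 libraries had no annotation in the deposited files. Named LTR retrotransposons took 10.2% of Siwi, 6.55% of Ago3, and 8.18% and 9.99% of DQAD reads. Named LINEs took 7.94%, 6.54%, 6.29% and 6.68%.

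Siwi and Ago3 piRNAs paired through the 10-nt overlap of the ping-pong cycle. Of the Siwi reads, 36.4% had an Ago3 partner whose 5′ end overlapped by 10 nt on the opposite strand, against a median of 3.38% at the other overlaps from 1 to 20 nt (z score 17.5). Of the Ago3 reads, 42.8% had a Siwi partner (z score 16.2). Within a library the share was 27.4% for Siwi and 28.8% for Ago3. DQAD piRNAs carried the same signature, with 26.1% and 27.0% of reads paired within their own library. The medians at the other overlaps were 4.59% and 8.35%, so replicate 2 stood less far above its background. Counting each distinct sequence once, the shares were 10.5% and 11.8%, against medians of 3.25% and 6.26%. DQAD reads found an Ago3 partner at 10 nt in 28.3% and 25.5%, and a Siwi partner in 25.7% and 23.5%. An overlap of 10 nt was the highest of the 20 in each of the 10 pairs tested.

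**Figure D2:**
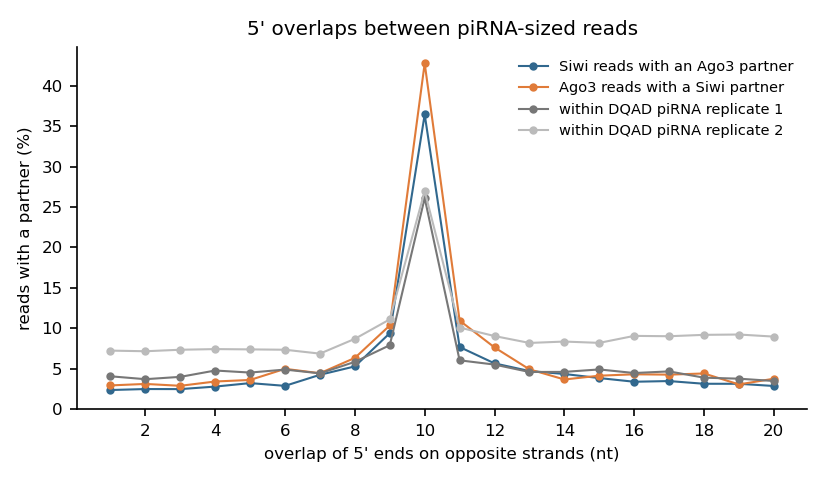
Share of piRNA-sized reads (vertical axis, %) with a partner on the opposite strand at each overlap of 5′ ends from 1 to 20 nt (horizontal axis), for Siwi reads against Ago3, Ago3 reads against Siwi, and each DQAD library against itself (1 line each). All 4 lines peak at 10 nt, between 26.1% and 42.8%.

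DQAD piRNAs held more reads of Siwi-biased than of Ago3-biased species. Species, defined by their first 20 nt, were classed by a 2-fold difference between the untransfected immunoprecipitates, which gave 21971 Siwi-biased, 16047 Ago3-biased and 4936 unbiased species. Siwi-biased species started with U in 91.8% of cases, and Ago3-biased species had A10 in 89.4%. Siwi-biased species held 42.7% and 38.5% of DQAD reads, and Ago3-biased species 14.1% and 14.9%. Species found in Siwi at any level held 76.2% and 71.1%, and those found in Ago3 71.2% and 67.9%, many of them shared. A further 18.9% and 23.98% of DQAD reads belonged to species seen in neither immunoprecipitate. Across 26542 species, which are not independent replicates, log abundance in DQAD replicate 2 correlated with Siwi at r = 0.585 (rho 0.513) and with Ago3 at r = 0.295. DQAD replicate 1, made with the other kit, correlated with Siwi at r = 0.112 and with DQAD replicate 2 at only r = 0.185.

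Per annotation name, tRNA and other non-transposon RNA had higher and transposons lower median values with DQAD than in the PIWI immunoprecipitates, but almost no single name passed the test. The list of other RNA (tRNA, microRNA and structural RNA, 59 measured members) had a median log2 fold change of 2.92 against Siwi and 1.91 against Ago3. Medians against Siwi were -1.44 for 153 LTR retrotransposons, -1.32 for 129 LINEs, -1.25 for 31 SINEs and -1.19 for 71 DNA transposons. Medians against Ago3 were -1.07, -0.99, -0.69 and -0.42 in the same order. With camera at a preset correlation of 0.01 the 5 lists passed in both comparisons, with adjusted p between 5.9e-16 and 0.0039. None of them passed with an estimated correlation (adjusted p = 0.483 against Siwi, and 0.551 to 0.584 against Ago3), and 0 members of any list passed edgeR's test singly over all names. Adjusted over the list alone, 1 other RNA name passed against Siwi, and 0 names passed in any other list or comparison. The estimated correlations rested on 1 residual degree of freedom, where a list can hardly pass. The failure of the lists with them therefore does not count against the lists. As a share of annotated reads the LTR list did not stand apart, with 33.6% in Siwi, 24.9% in Ago3, and 29.1% and 32.9% in DQAD. Only LINEs, among the transposon lists, were lower in both DQAD libraries (20.7% and 19.5%) than in Siwi (23.7%) and Ago3 (21.9%). DNA transposons took 6.57% in Siwi, 3.02% in Ago3, and 5.24% and 7.28% in DQAD, and SINEs 1.02%, 0.999%, 0.822% and 1.31%, so in replicate 2 both shares were above those of the PIWI libraries. Other RNA took 1.94%, 1.77%, 3.40% and 3.76%.

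Against Siwi, 0 of 2098 names passed edgeR's quasi-likelihood test (155 at an unadjusted p under 0.05, and 1 with DESeq2). Against Ago3, 1 passed, the gene model BGIBMGA008197, lower with DQAD (log2 fold change -4.29, SE 0.81, adjusted p = 0.00027 by edgeR's quasi-likelihood test), with 828 and 2383 reads in DQAD and 17615 in Ago3, while 0 passed with a filter of 50 reads, and DESeq2 called 1 name, higher with DQAD, and gave no adjusted p for 1383. The lone PIWI library was assumed to vary like the DQAD pair, whose libraries were made with different kits and gave the only residual degree of freedom, so p-values rest on that assumption. At the estimated spread the test against Siwi recovered 0% of simulated changes of log2 2 or 4. A second set of repeat names was scarcer in DQAD replicate 1, with 0.777% of reads against 3.61% in Siwi, 2.91% in Ago3 and 5.36% in replicate 2: of 195 abundant Siwi sequences with such names it held 2.56%, against 76.8% of unannotated ones and 100% of the 195 in replicate 2, and the transposon medians above include these names. Without them the medians against Siwi were -1.84 for 11 LTR retrotransposons and -1.92 for 17 LINEs. Without that set, an alternative chosen after seeing the data, 206 of 1490 names passed against Ago3 (110 higher and 96 lower) and 0 against Siwi by edgeR, under the same assumption (596 at an unadjusted p under 0.05), with DESeq2 not run there. There, 5 of 59 other RNA names were higher and 2 lower than in Ago3, a share of rises close to that of all names, and the list no longer passed (adjusted p = 0.158), and 4 of 17 LINE names were lower. The 4 highest by the naming rule were tRNA names: Gln(CTG) at log2 5.94 (SE 1.29, adjusted p = 0.044 by edgeR's quasi-likelihood test), Gly(TCC) at 4.88, Lys(CTT) at 4.75 and Phe(AAA) at 4.49. The lowest were the gene models BGIBMGA013200 at -5.23 and BGIBMGA008197 at -4.68.

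The reporter carried 14 sites of 28 nt for endogenous piRNAs, set 78 nt apart, and the experiment asked where Siwi and Ago3 reads and Vasa-bound 12-mers arise on it. Reads antisense to the reporter are the guides, and sense reads come from the transcript. Sense reads made up 0.428% ± 0.344 (SD, n = 2) of reporter reads in Siwi, 49.9% ± 25.2 (n = 2) in Ago3 and 97.6% ± 0.925 (n = 2) among the 12-mers. The Ago3 replicates lay at 32.1% and 67.7%, both far above Siwi at 0.185% and 0.671%. Of the sense Ago3 reads, 86.9% ± 3.40 (n = 2) began at the position that gives a 10-nt overlap with the guide, against 28.5% ± 4.14 (n = 2) of the few in Siwi. Antisense reads began at the guide 5′ end in 89.9% ± 3.199 for Siwi and 87.2% ± 0.392 for Ago3 (n = 2 each). With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, the value it gave for each of these measures. All these libraries were made with the NEBNext kit.

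In untransfected cells the guides of the reporter were present. Antisense matches numbered 22833 in Siwi (9307 RPM) and 4536 in Ago3 (2008 RPM). Sense matches numbered 0 in Siwi, below the floor of 1.22 RPM that 3 counts allow, 6 in Ago3, and 13 and 30 in the DQAD piRNA libraries. A read with the 10-nt overlap would run into the artificial spacer, so these counts give no measure of endogenous products.

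Each tested sense 5′ end was higher in Ago3 than in Siwi, which restates the difference in sense share and is no separate result. Relative to all reporter reads, 138 of 192 tested 5′ ends passed edgeR's quasi-likelihood test, 72 higher and 66 lower in Ago3. The balance was 34 to 12 with reads of 26 to 30 nt and 59 to 22 with the untransfected libraries added. The latter held no reporter, with 0 sense reads in Siwi and 6 in Ago3, so that alternative says nothing about sense ends. All 57 sense ends were among the higher, with log2 fold changes from 2.37 to 11.54 and a median of 6.44 when the 8 ends that had no Siwi read were set at their bound. Siwi held 340 and 937 sense reads in all, and Ago3 11883 and 61209. The read filter was therefore met mainly through Ago3, and a rise of all tested sense ends followed from these totals. With sense ends scaled among themselves, an alternative chosen after seeing the data, 30 of 57 passed (16 higher and 14 lower). That scaling centres them by construction and so shows only how they differ from one another. With antisense ends treated likewise, 67 of 135 passed (35 higher and 32 lower). Relative to all reporter reads, of 135 antisense ends 15 were higher, 66 lower and 54 did not pass. That excess of falls cannot be told apart from the larger sense share of reporter reads in Ago3. The 11 sense ends with a 10-nt overlap that could be tested rose by a median of 9.31 on the log2 scale, from 6.02 at site 6 to 11.54 at site 11. Site 11 gave 1714 and 16792 reads in Ago3 and between 7 and 16 in Siwi (log2 11.54, SE 1.51, adjusted p = 0.00084 by edgeR's quasi-likelihood test). Sites 13, 4, 12, 1 and 14 followed, at 10.55, 10.20, 10.07, 9.95 and 9.31. Sense ends 223, 858, 686 and 1086 had no Siwi read, and against a floor of 3 reads over the group they were at least 325.1-fold, 117.7-fold, 67.7-fold and 57.6-fold higher. Sense end 223 lies 2 nt upstream of the place where the product of site 3 would begin. Among calls with a mean of at least 100 CPM and no overlap, the 10 largest falls were antisense ends inside the guides of sites 5, 11, 12 and 1, past their 5′ ends. They were led by positions 377 at -5.83, 851 at -4.83 and 378 at -4.60. Over all tested antisense ends the lowest value was -7.06. At the guide 5′ ends themselves, 6 were lower and 7 did not pass. The guide of site 6 was the exception, higher in Ago3 by 4.62 on the log2 scale (SE 0.69, adjusted p = 0.0014 by edgeR's quasi-likelihood test). That guide was also higher in Ago3 than in Siwi in untransfected cells, so its excess was not particular to reporter-transfected cells. The count of calls rests on every library: without 1 of the 4 it fell to between 0 (without Siwi replicate 1, where 73 ends had an unadjusted p under 0.05 by edgeR and DESeq2 was not run) and 43 (without Ago3 replicate 1, 33 higher and 10 lower). It was 27 without Ago3 replicate 2 (23 higher and 4 lower) and 33 without Siwi replicate 2 (29 higher and 4 lower).

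**Figure D3:**
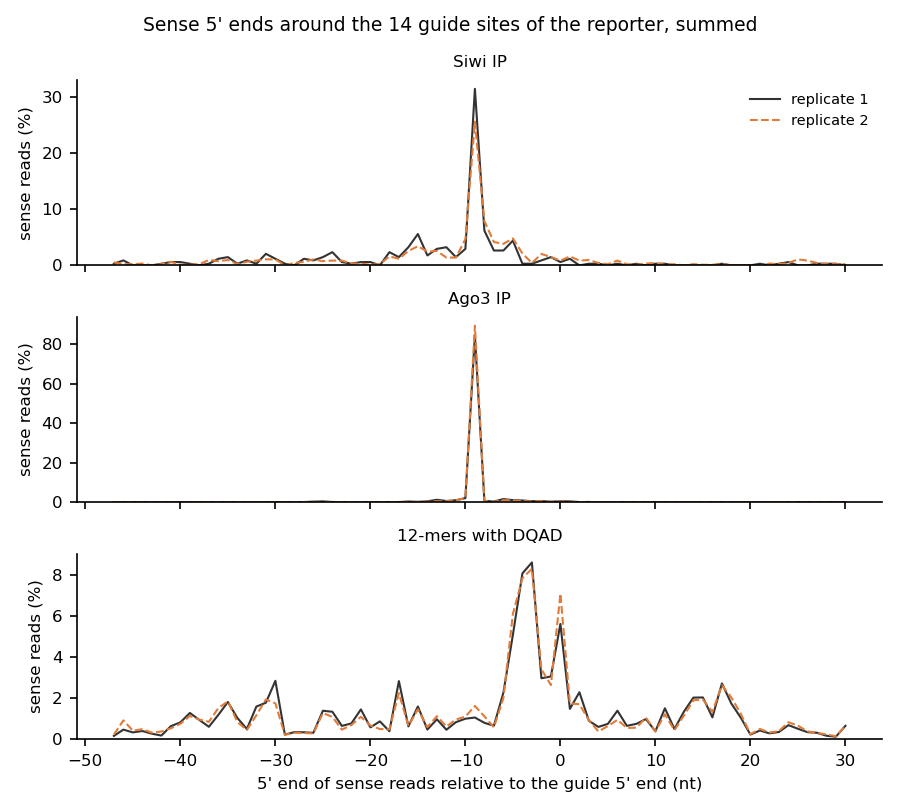
Share of sense reads (vertical axis, %) by the distance of their 5′ end from the guide 5′ end (horizontal axis, nt, negative upstream on the transcript), summed over 14 sites, with 1 line per replicate. Ago3 reads peak at -9 nt (84.5% and 89.4%), the 10-nt overlap, and 12-mers at -3 nt (8.59% and 8.28%).

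Ago3 products were unevenly spread over the sites. Sites 1, 11, 4 and 13 gave 21.4% ± 3.85, 20.9% ± 9.20, 13.5% ± 4.13 and 11.5% ± 2.38 of sense Ago3 reads (SD, n = 2). Sites 3, 5 and 8 gave 0.014% ± 0.0038, 0.069% ± 0.0021 and 0.052% ± 0.021 (n = 2). These shares are for the 10-nt overlap alone: at site 3 the Ago3 replicates had 55 and 329 sense reads that began 2 nt upstream of it (0.463% and 0.538%), and 2 and 7 at it. Their guides were not rare: the guide of site 3, TCTTCGATCTTCCTCAAATGAATCCGGC (chromosome 11 from 16569493 to 16569520, minus strand, no annotation), made up 21.6% ± 1.39 of antisense Siwi reads, the highest of the 14. The guide of site 8 took 13.2% ± 3.95 and that of site 5 took 4.89% ± 0.147 (n = 2). Values of r over sites are for shares on a log scale with a small constant added, so sites with hardly any reads weigh on them. Across the 14 sites, product share in Ago3 had r = -0.401 with guide share in Siwi (permutation p = 0.156, adjusted p = 0.391, rho = -0.363 with p = 0.204, and r = -0.206 without the 2 farthest sites). It had r = 0.598 with the share of 12-mers 3 to 5 nt upstream of the guide 5′ end (permutation p = 0.026, adjusted p = 0.13 over 5 relations, rho = 0.546 with p = 0.046, and r = 0.580 without the 2 farthest sites), which did not pass after adjustment. The guide of site 6, TTTGTTAATAATCTGTAGTGTATCGTGT (chromosome 13 from 14661690 to 14661717), took 0.690% ± 0.12 of antisense Siwi reads and 26.3% ± 1.74 of those in Ago3 (n = 2), and site 6 led the 12-mers.

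**Figure D4:**
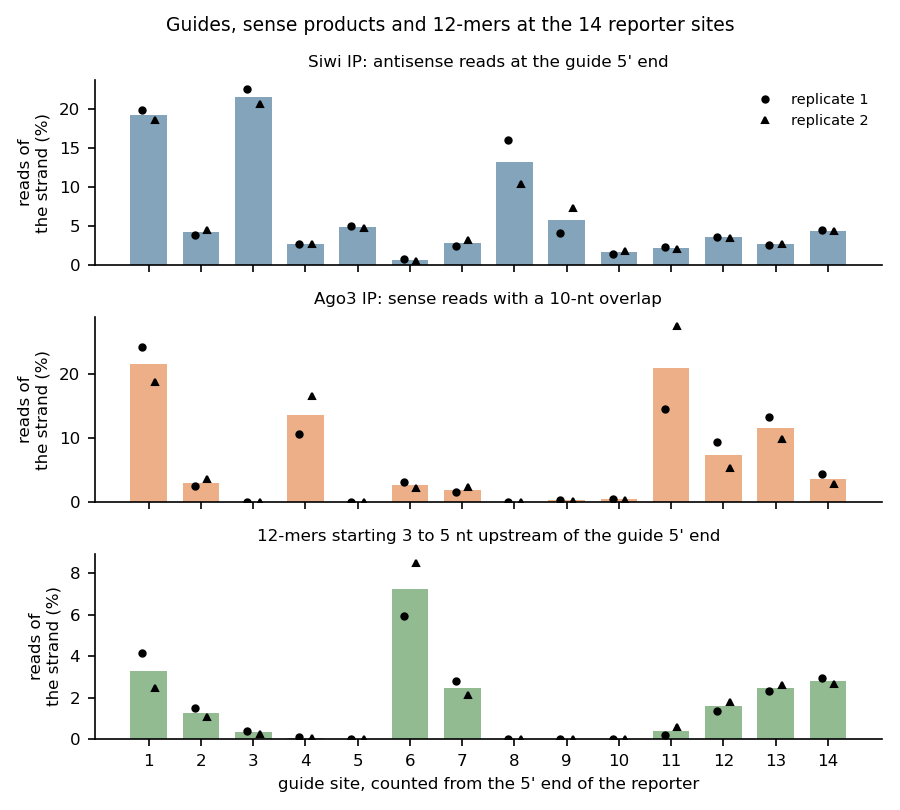
Guide reads in Siwi, sense products in Ago3 and 12-mers at each of the 14 sites (horizontal axis), as a share of reads of that strand (vertical axes, %), with bars for means and points for the 2 replicates. Sites 3, 5 and 8 have guides (21.6%, 4.89% and 13.2%) and hardly any Ago3 reads with the 10-nt overlap.

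The reporter 12-mers bound by DQAD came from the transcript strand and, summed over the 14 sites, clustered near the guide 5′ end. Of the sense 12-mers, 22.0% ± 0.334 (SD, n = 2) began 3 to 5 nt upstream of the guide 5′ end, and the top position was 3 nt upstream in both libraries, at 8.59% and 8.28% against medians of 0.791% and 0.830% elsewhere. The position 3 nt upstream lies 6 nt inside the Ago3 product. Another 6.34% ± 1.04 (n = 2) began opposite the guide 5′ end itself. Sense 12-mers that began inside a guide site made up 55.4% ± 0.871 (n = 2). Site 6 gave 7.22% ± 1.83, site 1 3.30% ± 1.18 and site 14 2.78% ± 0.204 of sense 12-mers in the 3 to 5 nt window, while sites 9 and 10 had 3 reads each in replicate 1 and 0 in replicate 2. The clustering was not seen at every site. Of the sense 12-mers in the 78-nt unit of a site, this window held 46.6% and 55.0% at site 6 and 58.4% and 53.6% at site 1. At sites 4, 5, 8, 9 and 10 it held at most 2.05%, less than an even spread of starts would give. The remaining sites lay between. In DQAD 12-mer libraries without the reporter, 12-nt sense matches numbered 576 and 1299 and antisense matches 384 and 1183, so that 60.0% and 52.3% were sense. The effect of the reporter on 12-mers could not be tested, because the reporter files share neither library totals nor features with these libraries.

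Endogenous 12-mers lay on the same strand as Ago3 piRNAs more than on the opposite strand. Averaged over the start positions inside a piRNA, the ratio of same to opposite strand was 2.38 and 1.98 in the 2 libraries for Ago3 piRNAs, and 1.77 and 1.42 for Siwi piRNAs. Of sampled 12-mers, 41.9% and 37.2% lay inside an Ago3 piRNA on the same strand, against 13.1% and 14.8% after shuffling. On the opposite strand 26.2% and 24.9% did, against 9.05% and 10.7%. The ratio of same to opposite strand was thus 1.60 and 1.49 for 12-mers and 1.44 and 1.38 for shuffled ones. A ratio above 1 therefore also arose by chance. As shuffled 12-mers matched less often, the ratios do not measure how much of the strand difference was chance. For Siwi piRNAs the ratio was 1.40 and 1.21, against 1.35 and 1.14 after shuffling. Inside a Siwi piRNA on the same strand lay 43.3% and 35.6%, against 13.4% and 14.6%. The favoured start was 5 and 6 nt inside the Ago3 piRNA, although at only 1.10 and 1.07 times the median of the other starts. Among Ago3 species with at least 10 reads, 25.1% had a 12-mer starting at offset 5 in replicate 1, the highest there, against 23.8% at offset 0. In replicate 2 offset 0 was the highest at 49.6%, ahead of offset 6 at 46.4%, so the libraries did not share a preferred start. The leading 12-mers were CGGCTGTTAACC, annotated Asn(GTT), in replicate 1 at 5488 RPM, and GTTGGCCTCAGATC without annotation in replicate 2 at 14449 RPM. Named repeats held 29.5% and 25.3% of 12-mer reads, LTR elements alone 14.4% and 12.5%. These names, and the label Asn(GTT), come from the 1 place given for each sequence. Of 12-nt sequences only 3.22% and 2.67% were placed on the plus strand, so that place is 1 of several possible. The names therefore do not show where the 12-mers came from, and no chance level was computed for them. The 12-mer libraries were made with different kits, 1 library each.

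Long RNA bound by DQAD held transposon transcripts that piRNAs match. Among its 48-nt reads, 18.8% were named repeats, 24.9% gene models and 56.2% without annotation. The gypsy-like LTR element LTR-BM|gypsy-Ty3-like alone took 8.83%, although 11.5% of its reads were runs of nearly 1 base (40 nt or more of 48), without which its share was 7.82%, and the LINEs L1Bm-2 and HOPEBm2 took 1.54% and 1.02%. Siwi piRNAs matched 25.9% of long reads on the same and 22.6% on the opposite strand, and Ago3 piRNAs 25.5% and 20.3%. In named repeats these shares rose to 54.0% and 54.2% for Siwi and 51.0% and 49.1% for Ago3, and in gene models they were 10.01% and 4.30% for Siwi and 11.6% and 4.53% for Ago3. DQAD piRNAs, which brought 270262 and 443590 species against 212673 for Siwi and 177605 for Ago3, matched 36.4% and 40.9% on the same and 23.2% and 26.7% on the opposite strand. In gene models they matched 26.2% and 27.0% on the same and 5.51% and 5.55% on the opposite strand, and in named repeats on the opposite strand DQAD replicate 1 (53.6%) lay below Siwi. Reversed piRNA sequences, a measure of chance matches, reached at most 0.0186% of all long reads. There was 1 library, hence no replicate check, and no long RNA from another immunoprecipitate to compare with.

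MicroRNAs, which bind Argonaute proteins outside the PIWI clade, were rare in these libraries, most of whose reads were of piRNA length. In the length window used for base composition lay 5 of 40 reads annotated as microRNA in Siwi and 2 of 118 in Ago3. In the DQAD replicates 28 of 330 and 23 of 1188 did. The values therefore cannot tell low background from read lengths that leave microRNAs out, and differences between libraries have the same limit. The 14 conserved microRNAs examined reached 11.4 RPM in Siwi, 28.3 in Ago3, and 144.3 and 230.6 in the DQAD piRNA libraries. Within the NEBNext kit the DQAD value was 230.6. Bantam stood at 73.3 RPM in DQAD replicate 2 and 1.05 in replicate 1, and miR-184 at 28.2 and 55.3. These values rest on the first 18 nt: of the 187 bantam reads in replicate 2, 0 matched the whole sequence.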

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

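The tests in this part were chosen only after the result was seen. Reporter 12-mer libraries were made from a gel band of about 12 nt, and no comparison looked at their reads of piRNA length apart, which are within the totals and, when sense, within the sense shares. They held 14 and 8 reporter reads of at least 20 nt, above the 3 counts that a count of 0 allows, or 0.0126% and 0.00723% of their reporter reads. Of these, 14 and 7 were sense, and 0 began at the 10-nt overlap that marks an Ago3 product. No group held the 4 samples needed to look for a library far from the others.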

How the results depend on the processing

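The alternatives without the second set of repeat names, and those with sense or antisense ends scaled alone, were tests chosen only after the result was seen. Of 143 alternatives of 42 results, 67 counted as kept, 24 were weaker, 8 stronger, 43 moved and 1 reversed. Kept meant a value within its spread, a number of calls near the main one, or a list on the same side of the threshold. On the reporter, 128 calls with RLE and 117 with DESeq2 counted as kept against 138. The cause of a change was not tested unless stated. Of the 67, 32 left out 1 library of a pair, which cannot move a mean by 1 SD, so they show nothing.

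Ago3 against Siwi on the reporter (138 calls) gave 209 with no filter, where more ends were tested, and fewer where fewer were tested: 64 at 50 reads, 46 with reads of 26 to 30 nt (34 higher and 12 lower). Sense ends alone gave 30 (16 higher and 14 lower) and antisense ends alone 67 (35 higher and 32 lower), each centred on its own strand. It gave 81 with untransfected libraries added (59 higher and 22 lower), which held no reporter and so say nothing about sense ends. Without 1 library it gave 0 to 43, each with 1 library in a group, assumed to vary like the others. With the replicate block it gave 141. The deviations of same-numbered Ago3 and Siwi libraries correlated at 0.261 over 192 ends. As this rests on 2 pairs, it cannot settle whether equal numbers were paired. DQAD against Siwi (0 calls) gave 5 with RLE, 1 with DESeq2, 4 with no filter and 1 at 50 reads. DQAD against Ago3 (1 call) gave 33 with no filter, 6 with reads of 26 to 30 nt, 0 at 50 reads, 206 without the second set, and 1 with DESeq2, higher where the main call was lower. No paired analysis was possible for the DQAD tests because the untransfected groups hold 1 library each, and leaving out a library left no residual degrees of freedom. With an estimated correlation each list lost its call, at adjusted p = 0.483 against Siwi and 0.551 against Ago3 (SINEs 0.584). Without the second set SINEs lost it against Siwi (0.0731), and LTR elements (0.0723), SINEs (0.231) and other RNA (0.158) against Ago3.

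Counting each distinct sequence once, U1 was 73.0% in Siwi, 45.6% in Ago3 and 49.0% with DQAD, and A10 38.6%, 63.6% and 40.4%. The 10-nt overlap was 16.9% for Siwi on Ago3, 19.9% for Ago3 on Siwi and 11.2% within DQAD, the 12-mer strand ratio 1.31 for Siwi and 1.56 for Ago3, and the long RNA match 22.8% for Siwi opposite and 21.8% for Ago3 same strand. At all lengths U1 was 87.0% and 38.99% and A10 39.5% and 79.0% (Siwi, Ago3). At 23 to 32 nt they were 87.6%, 39.3%, 39.7% and 80.9%, and without the 100 most abundant 87.3%, 42.4%, 40.2% and 82.2%. Overlaps without these were 35.0%, 40.8% and 25.8%, and with at least 2 reads 31.03%, 37.0% and 22.6%. Siwi-biased species took 35.0% of DQAD reads at 4-fold and 33.9% by whole sequence, Ago3-biased 12.3% and 11.02%, and species in neither 32.5% by whole sequence. The Ago3 12-mer ratio was 3.37 with piRNAs of at least 10 reads. In the length window, guide 5′ ends held 98.0% (Siwi) and 93.5% (Ago3) and the 10-nt overlap 90.4% (Ago3). Matched whole, microRNAs stood at 3.67, 8.41 and 91.6 RPM in Siwi, Ago3 and DQAD.

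Not run were unique alignments (not marked in the files), reporter immunoprecipitates as the sharing standard and RPM on the reporter (both need other reads of those libraries), 1 mismatch (all reads equalled the reporter), the fit over 3 groups, and all alternatives of the reporter effect on 12-mers. Depth leaves the 8 sense ends without a Siwi read as lower bounds only.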

Other observations

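In this part, all tests on sites 3, 5 and 8, the test of the kit, and the tests on guide changes other than the one of amplification over the 14 sites were chosen only after the result was seen. The guides of the reporter differed in how their share changed between untransfected and reporter-transfected Siwi immunoprecipitates. The ratio of shares ran from 0.153 at site 6 to 74.7 at site 13 (95% interval 40.6 to 156), and without site 13 up to 6.05 at site 14. Untransfected reads were counted by the first 20 nt of the guide. For site 13, guide TTCCTTATGTCGGTCGTGATTTTCCGTT, 10 such reads in Siwi stood against 8631 in the reporter libraries, and as 0 reads of the 4 genome-aligned piRNA libraries continue as this guide past nt 25, its ratio compares related rather than equal sequences. At site 10 too, only 24.6% of the reads with 0 to 3 other bases equalled the guide.

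Few sense Ago3 reads with the 10-nt overlap arose at sites 3, 5 and 8, although within 3 nt of that position site 3 had 0.480% and 0.554%, no lower than site 9 (0.446% and 0.266%). The tables argue against fewer guides, since 3 of the 3 sites were among the upper 7 by guide share in both Siwi libraries, and against a mismatch between guide and site, since among reads of the 4 genome-aligned piRNA libraries with 0 to 3 other bases over nt 1 to 26 of the guide, 100% equalled it at each of the 3. Loss in trimming of reads holding the adaptor-like stretch AGATCGAAGAG at positions 225 to 235 is argued against at sites 5 and 8, where 0 products hold it, but stays open at site 3: 57 sense reads of the lower Ago3 library hold it, so not all were lost. No cleavage at these sites may be an explanation and stays open: 0 of the 3 were among the upper 7 by 12-mer share, though sites 4 and 11 had few 12-mers (0.0763% and 0.410%) and many products.

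DQAD libraries held more reads with neither U1 nor A10 than either PIWI library. The kit alone is argued against by 17.1% in the NEBNext DQAD library, against 9.69% in Ago3. Reads annotated as gene, tRNA, microRNA or structural RNA are argued against as the only source. Without them 12.3% and 16.9% remained, against 9.87% in Ago3 treated alike. Among those annotated reads the share was 17.8% and 18.6% with DQAD, against 4.85% in Siwi and 8.50% in Ago3. Most reads carry no annotation, so fragments of RNA without annotation could not be removed and stay open. RNA of species not seen in either PIWI immunoprecipitate stays open as an explanation. Among species seen in either, the share was 7.87% and 9.28%, and among the others 38.1% and 47.1%. The PIWI libraries hold only 5.58% and 9.69% of such reads, so choosing species found in them lowers the share by construction. The split therefore cannot decide the question, and where the species seen in neither come from was not tested.

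The uneven change of guides exceeded counting error of rare guides at the 11 sites with like sequences (all but 10, 13 and 14). The lower bound was 2.76 at site 8, against an upper bound of 0.164 at site 6. Amplification by the reporter predicted that the log2 ratio rises with product share. No such rise was seen, with rho = -0.0813 over the 14 sites (permutation p = 0.786) and -0.418 over the 11. So few sites, set against 1 untransfected library, cannot exclude a weaker relation, so amplification stays open. Another 5′ end of the guide in untransfected cells is argued against at site 13, where reads with guide nt 2 to 19 were 1.10 times those with its first 20 nt, but may explain site 14, where they were 3.94 times those and the ratio counted by them was 1.59. A guide sequence missing from the genome used for alignment was tested next at site 13 by its first 24 nt, and the 10 reads of the 4 genome-aligned piRNA libraries that begin with them counted against it. Looking at those reads showed that the bound lay 5′ of a base difference, so the test was rewritten: 7 reads reach nt 26, counted from 1 at the guide's 5′ end, all with G26A and 0 as the guide (chromosome 1 from 7083504 to 7083531, minus strand, LTR-INV|PAO). A guide from a sequence absent from that genome may therefore explain site 13 alone, as a hypothesis built on these reads after 2 failed tests, and the differences among the 11 sites stay unexplained.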
